A study of Mus musculus with 6 samples.

How the data were processed

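RNA was measured in spleen cells of 3 D3TA and 3 WT mice, 1 library per mouse, as named in the labels. Per the labels' protocols, messenger RNA was purified with poly-T beads and copied with random hexamers, and no strand-marking step is described. The submitters' processing notes name CASAVA, FastQC, Trim Galore, HISAT2 and DESeq2 and the genome build mm10, without versions or roles. The counting program and its annotation are not stated there.

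The deposited table is titled as raw counts, but its values are a signal: counts that the authors had divided by a size factor per library, on the evidence of the values. In each library the values were whole multiples of a fixed step between 0.864 (D3TA-3) and 1.12 (WT-2). Dividing by the step gave whole reads within 0.001 for 100% of 149436 values. The design had assumed raw counts with edgeR's quasi-likelihood test. Because the unit differed, limma on log2 of the deposited values became the main test, and count tests on recovered reads became alternatives. Recovered reads per library ranged from 14944622 to 19456838, and 3 reads correspond to a normalized count of 2.59 to 3.36. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

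All 24906 listed genes had at least 2 reads in total. Symbols and coordinates came from GENCODE release M21 on GRCm38, the assembly also called mm10, which held 24860 of the 24906 gene identifiers.

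Genes with a normalized count of at least 10 in at least 3 libraries were tested (15564). The values were fitted as log2(normalized count + 1) with limma 3.58.1 (trend and robust empirical Bayes), with genotype as the factor and no covariate, and adjusted by Benjamini-Hochberg at 0.05, 2-sided. Standard errors are limma's moderated errors for genes and unpooled errors of library scores for lists. Folds are 2 raised to the log2 difference. Before the data were examined, 28 gene lists for cell types and programmes and a list of sex-linked genes were fixed. Of these, 27 had at least 3 tested members and entered camera with its preset correlation of 0.01, with adjustment over those 27. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone.

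Named genes followed a rule fixed at the same time: Ccnd3, the 6 genes per direction with the largest change past the threshold (0 genes met this), the 2 members with the smallest p of each cell type list and the 1 such member of each other list. This gave 43 genes, and any other gene is said to be named after its values were seen. Sex-linked genes are given as values per library.

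Alternatives were other scalings (TMM, RLE, library size only, upper quartile), filters, pseudocounts of 0.5 and 5, removal of immunoglobulin, T cell receptor and hemoglobin genes, each library left out, the replicate number as a block, limma-voom, edgeR 4.0.16 and DESeq2 1.42.0. Terms for libraries with Y-linked reads and for libraries with more than 5% hemoglobin reads, the pseudocounts, and TMM factors and the filterByExpr filter in the limma fit were added after the data were seen. A fit without both D3TA-1 and WT-2 was also added then. The calculations used R 4.3.3, and figures used Python 3.11.15 with matplotlib 3.10.9.

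The main test was checked on simulated counts for the 15564 genes, with 100 genes changed 4-fold and 100 changed 16-fold in each of 5 runs. The changed genes were drawn only from genes with a mean normalized count of at least 50, so recovery of lower genes was not checked. At the libraries' own dispersion (median 0.150) the main test recovered 71.0 of the 4-fold and 98.8 of the 16-fold genes on average, with 12.8 false calls. At a dispersion of 0.02 it recovered 100 of each, with 12.8 false calls. The simulated counts were drawn independently for each gene, without the spread that the real libraries share across genes. The recovery rates therefore need not hold for the real libraries, where Mpo, at a 20.8-fold difference, did not pass.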

Results

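Gene expression was measured by sequencing polyadenylated RNA from spleen cells of 6 C57BL/6J mice aged 12 to 16 months. The D3TA group held 3 mice with a CRISPR/Cas9-made knock-in in Ccnd3, the gene for cyclin D3, which replaces threonine 283 with alanine (T283A). The other group held 3 age-matched wild-type (WT) mice. Per the series record, the knock-in line was kept heterozygous, and mice of this age show advanced myeloproliferative neoplasm (MPN). The comparison addresses how the spleen transcriptome of such mice differs from that of WT mice. The libraries held 15545775 (D3TA-1), 16468904 (D3TA-2), 17482873 (D3TA-3), 16620906 (WT-1), 14944622 (WT-2) and 19456838 (WT-3) reads assigned to genes. Values are normalized read counts, and differences are D3TA minus WT on the log2(normalized count + 1) scale. That scale tends to understate the change of low genes, but a gene with a library at or near 0 can show a larger fold, or another direction, than its group means.

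The libraries differed in ways other than genotype. Hemoglobin transcripts took 6.39% of reads in D3TA-1, 6.75% in D3TA-2 and 6.57% in WT-3, but 1.91% in D3TA-3, 1.63% in WT-1 and 1.40% in WT-2. Xist was at 10384 in D3TA-1, 9042 in D3TA-2, 2628 in WT-2 and 1195 in WT-3, where Y-linked genes were near 0. D3TA-3 and WT-1 carried Y-linked transcripts, with Ddx3y at 1116 and 1162 and Xist at 8.64 and 4.78. WT-2 listed 8449 genes at 0, against 3193 to 5170 in the other 5 libraries, and lay at 124.6 on the first principal component (42.0% of variance), where the other 5 lay between -83.8 and 15.7.

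Spleens of D3TA mice carried more transcripts of neutrophil granule genes in each of the 3 libraries than any WT spleen. Transcripts of B cells were lower in each of the 3, and transcripts of mitosis were higher. Mpo, the myeloperoxidase of neutrophil primary granules, averaged 8788 ± 6539 (SD, n = 3) in D3TA and 329 ± 7.52 (SD, n = 3) in WT. Fcer2a, the low-affinity IgE receptor CD23 of mature B cells, averaged 443 ± 208 in D3TA and 2100 ± 791 in WT (SD, n = 3 each). The neutrophil transcripts were highest in D3TA-1 and lowest, among the D3TA libraries, in D3TA-3.

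Gene by gene, no difference passed the transcriptome-wide threshold. Of 15564 genes tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.0945, shared by 26 genes. At an unadjusted p under 0.05 there were 1542 genes, 946 higher and 596 lower in D3TA, where 778 would be expected by chance. The 3 D3TA values did not overlap the 3 WT values for 1273 genes above and 1065 genes below, together 15.02% of genes, against 10% by chance. On recovered read counts, edgeR's quasi-likelihood test called 0 genes (1609 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 472, of which 341 were higher and 131 lower in D3TA. Of the 131 lower genes, 41 were immunoglobulin genes. DESeq2 was fitted without the count filter, and 297 of its 341 higher and 125 of its 131 lower genes were tested in limma. Leaving out D3TA-3 raised limma's count to 306 (248 higher, 58 lower). A term for libraries with Y-linked reads gave 15 calls and a term for libraries with a high hemoglobin share gave 11, Mpo, Elane and Ngp among them in both.

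Transcripts of the edited gene itself did not pass the test. Ccnd3 (ENSMUSG00000034165, chromosome 17, 47505051 to 47599691, GRCm38) had normalized counts of 7842, 3509 and 2424 in D3TA-1 to D3TA-3 and of 3086, 3064 and 2433 in WT-1 to WT-3. Its log2 difference was 0.51 ± 0.41 (SE), with an adjusted p of 0.713 in limma. Without D3TA-1 the log2 difference was 0.04, and without D3TA-3 it was 0.88. The edit changes a codon, so these counts do not check the genotype labels.

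Neutrophil granule transcripts rose in D3TA spleens. Of 12 tested genes of primary granules and early neutrophils, 11 lay above 0 and 9 rose at an adjusted p under 0.05 adjusted over the list alone (0 over all genes tested). The list score, the mean log2 value of its members, was 2.32 ± 0.58 (SE) higher in D3TA. Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413) was 20.8-fold higher, with a log2 difference of 4.38 ± 0.55 (SE), an adjusted p of 0.0945 over all genes and of 0.000109 over the list alone. Elane (ENSMUSG00000020125), which encodes neutrophil elastase, was 15.4-fold higher, at 4918 ± 3575 against 276 ± 116 (SD, n = 3 each). Cebpa, singled out after its values were seen as the member below 0, averaged 819 in D3TA and 1013 in WT.

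Among 21 tested genes of secondary granules and mature neutrophils, 20 rose, adjusted over the list alone (0 over all genes tested). The list score was 3.37 ± 0.85 (SE) higher on the log2 scale, a 10.4-fold difference. Ltf (ENSMUSG00000032496), which encodes lactoferrin, was 17.4-fold higher, at 34586, 19632 and 4024 in D3TA-1 to D3TA-3 and 1043, 722 and 686 in WT-1 to WT-3. Stfa3, named after its values were seen as the member that did not rise, averaged 4.44 in D3TA and 19.2 in WT. Ngp (ENSMUSG00000032484), neutrophilic granule protein, was 15.6-fold higher, at 37016 ± 28559 against 1865 ± 508 (SD, n = 3 each). Camera called both neutrophil lists as higher, with adjusted p values of 3.89e-12 for primary and 4.20e-26 for secondary granules, and neither call held with an estimated correlation (adjusted p = 0.430 for each). Between the 3 libraries with a high hemoglobin share (D3TA-1, D3TA-2 and WT-3) the secondary granule score was 3.57 higher in D3TA. Between the 3 with a low share (D3TA-3, WT-1 and WT-2) it was 2.18 higher. Here and for the lists below, such differences rest on WT-3 alone for WT, or on D3TA-3 alone for D3TA. The primary granule score was 2.47 and 1.497 higher in the same comparisons. Without D3TA-1, D3TA-2 or WT-1 in turn, the count of 9 for primary granules became 6 each time. The counts of 0 over all genes tested became 7 for primary and 17 for secondary granules without D3TA-3, 5 and 7 with the Y-linked term, and 3 and 6 with the hemoglobin term. Without D3TA-3 they also became 9 for erythroid, 8 for G2/M, 4 for G1/S, 4 for heme, 3 for B cell and 3 for interferon response genes, and at most 2 for any other list.

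**Figure D1:**
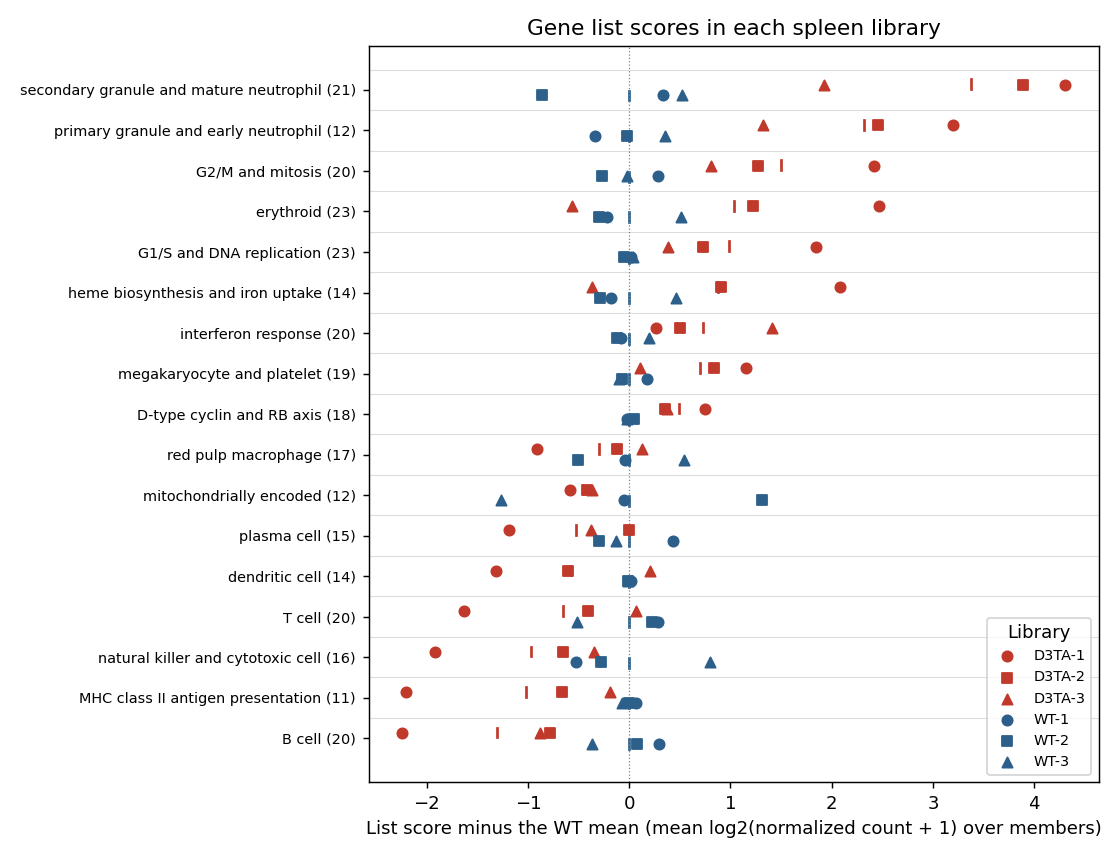
Gene list scores in each library for the 17 lists called by camera with its preset correlation, as the mean log2(normalized count + 1) over list members minus the WT mean. Points are libraries (red D3TA, blue WT), short vertical lines are group means, and the number of tested genes is in parentheses. The 3 D3TA libraries lie above the 3 WT libraries for both neutrophil lists, G2/M, G1/S, the D-type cyclin and RB axis and interferon response. They lie below the WT libraries for B cell and MHC class II genes.

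B cell transcripts fell in D3TA spleens. All 20 tested B cell genes lay below 0 and 15 fell, adjusted over the list alone (0 over all genes tested). The list score differed by -1.30 ± 0.51 (SE), a 2.47-fold lower level, with a camera adjusted p of 4.12e-16 and an adjusted p = 0.430 with an estimated correlation. Ighd (ENSMUSG00000104213), the constant region of the IgD receptor of mature naive B cells, was 3.32-fold lower, at 2683 ± 688 against 8937 ± 2348 (SD, n = 3 each). Fcer2a was 4.93-fold lower. The score difference was -1.14 between the high-hemoglobin libraries and -1.06 between the low-hemoglobin libraries. The count of 15 became 8 without D3TA-1 (mean -0.83), 6 without WT-1, 6 without WT-2 and 7 with the hemoglobin term. Without both D3TA-1 and WT-2 the count was 3, and 3 of the 20 members lay above 0.

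Genes of MHC class II antigen presentation lay lower as well. All 11 lay below 0, with a score difference of -1.02 ± 0.61 (SE) and a camera adjusted p of 1.15e-06 (adjusted p = 0.553 with an estimated correlation), and 0 passed over the list alone. H2-Oa, a chain of the class II modulator H2-O found mainly in B cells, averaged 958 ± 618 in D3TA and 2454 ± 644 in WT (SD, n = 3 each). The list score was 11.2 in D3TA-1, 12.8 in D3TA-2 and 13.2 in D3TA-3, against 13.4 to 13.5 in WT, and the score difference was -1.36 between high-hemoglobin and -0.22 between low-hemoglobin libraries. Without D3TA-1 the mean difference was -0.43, and without D3TA-3 9 members fell over the list alone. Plasma cell genes had 5 of 15 members above 0 and a score difference of -0.52, with a camera adjusted p of 0.00599 (adjusted p = 0.553 with an estimated correlation). The plasma cell call was lost without D3TA-1 (0.310) and without WT-1 (0.104), and the score difference was -0.46 between high-hemoglobin and -0.44 between low-hemoglobin libraries. Tnfrsf13b, a BAFF and APRIL receptor, was the member that fell over the list alone, from 3052 ± 297 in WT to 1267 ± 409 in D3TA (SD, n = 3 each). That count of 1 became 0 without D3TA-1, WT-1, WT-2 or WT-3, and 2 without D3TA-2. Ighg3 averaged 4798 ± 6507 against 23697 ± 17198, with overlapping groups, and its reads can be shared with other immunoglobulin constant genes.

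T cell and natural killer (NK) cell lists also lay lower. Of 20 T cell genes 19 lay below 0, with a score difference of -0.66 ± 0.57 (SE) and a camera adjusted p of 2.13e-06 (adjusted p = 0.553 with an estimated correlation). Lef1, a transcription factor of naive T cells, was the T cell gene that fell over the list alone, from 1030 ± 428 in WT to 215 ± 47.5 in D3TA, a 4.51-fold difference. Tcf7 was 2.01-fold lower without passing. The T cell difference was -0.51 between high-hemoglobin and -0.19 between low-hemoglobin libraries and -0.17 without D3TA-1, and without D3TA-3 7 members fell over the list alone. Without both D3TA-1 and WT-2 the T cell call was lost (camera adjusted p 0.422, mean -0.06, 9 of 20 members above 0). Of 16 NK and cytotoxic genes 12 lay below 0, with a score difference of -0.97 ± 0.63 (SE) and a camera adjusted p of 0.00208 (adjusted p = 0.553 with an estimated correlation). The NK call was lost without D3TA-1 (0.134) and without WT-3 (0.0919), and the score difference was -2.09 between high-hemoglobin libraries and 0.06 between low-hemoglobin libraries. The count of NK genes that fell over the list alone was 1, but 4 without D3TA-2 or WT-1 and 0 without D3TA-1, WT-2 or WT-3. Klra7 fell over the list alone, from 183 ± 151 to 17.3 ± 11.5, and Klra8 averaged 139 ± 116 in WT and 21.2 ± 17.6 in D3TA. Klra7 and Klra8 belong to the Ly49 receptor family, whose related genes can share reads, so each value is uncertain.

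Cell cycle transcripts were higher in D3TA. All 20 tested G2/M and mitosis genes lay above 0 and 19 rose, adjusted over the list alone (0 over all genes tested), with a score 1.501 ± 0.505 (SE) higher, a 2.83-fold difference. Bub1, a spindle checkpoint kinase, was 3.22-fold higher, at 1056, 649 and 420 in D3TA-1 to D3TA-3 and 195, 169 and 259 in WT-1 to WT-3. All 23 genes of G1/S and DNA replication lay above 0, with a score 0.98 ± 0.44 (SE) higher, but 0 passed over the list alone. Mcm6, a subunit of the replicative helicase, averaged 3804 ± 1316 in D3TA and 1651 ± 602 in WT (SD, n = 3 each). Of 18 genes of the D-type cyclin and RB axis 16 lay above 0, with a score 0.49 ± 0.13 (SE) higher. Rbl1, which encodes the pocket protein p107, averaged 1234 ± 418 and 623 ± 156. Camera's adjusted p was 5.45e-16 for G2/M, 4.42e-11 for G1/S and 0.00551 for the cyclin list (adjusted p = 0.430, 0.553 and 0.430 with an estimated correlation). The G2/M count of 19 fell to 0 without D3TA-1 and to 6 without WT-2, and the G2/M score difference was 1.87 between high-hemoglobin and 0.80 between low-hemoglobin libraries. The G1/S difference was 1.25 and 0.40, and the cyclin list's 0.58 and 0.36, in the same order. The G1/S mean was 0.56 without D3TA-1, with the Y-linked term 5 of its genes rose over the list alone, and without D3TA-3 19 did, with 4 of the cyclin list rising and 1 falling.

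Erythroid and megakaryocyte lists were called higher by camera, with 0 members passing over the list alone. Of 23 erythroid genes 22 lay above 0, with a score 1.04 ± 0.92 (SE) higher and a camera adjusted p of 2.34e-05 (adjusted p = 0.553 with an estimated correlation). Sptb, the erythrocyte beta-spectrin gene, was at 8831, 2357 and 739 in D3TA-1 to D3TA-3 and at 1130, 657 and 408 in WT-1 to WT-3. Ermap averaged 3198 ± 3079 and 752 ± 60.5 (SD, n = 3 each). The erythroid score difference was 1.33 between high-hemoglobin libraries and -0.31 between low-hemoglobin libraries. Hemoglobin genes are members of this list, so that split is not independent of its score. Without D3TA-1 the erythroid call was lost (mean 0.33, camera adjusted p 0.137). All 14 genes of heme biosynthesis and iron uptake lay above 0, at a mean of 0.87 with a camera adjusted p of 0.000324 (adjusted p = 0.553 with an estimated correlation). That call was lost without D3TA-1 (mean 0.27, adjusted p 0.182), and its score difference was 1.03 in the high-hemoglobin and -0.13 in the low-hemoglobin libraries. Slc11a2, the iron transporter DMT1, averaged 883 ± 414 in D3TA and 417 ± 93.9 in WT. Of 19 megakaryocyte and platelet genes 18 lay above 0, at a mean of 0.70 with a camera adjusted p of 0.000276 (adjusted p = 0.553 with an estimated correlation), and the difference was 1.10 in the high-hemoglobin and 0.05 in the low-hemoglobin libraries. Selp, which encodes P-selectin, averaged 53.3 ± 22.7 and 10.6 ± 4.07, and Itgb3 averaged 1861 ± 987 and 870 ± 269. Without D3TA-3, 18 erythroid, 11 heme and 8 megakaryocyte genes rose over the list alone.

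**Figure D2:**
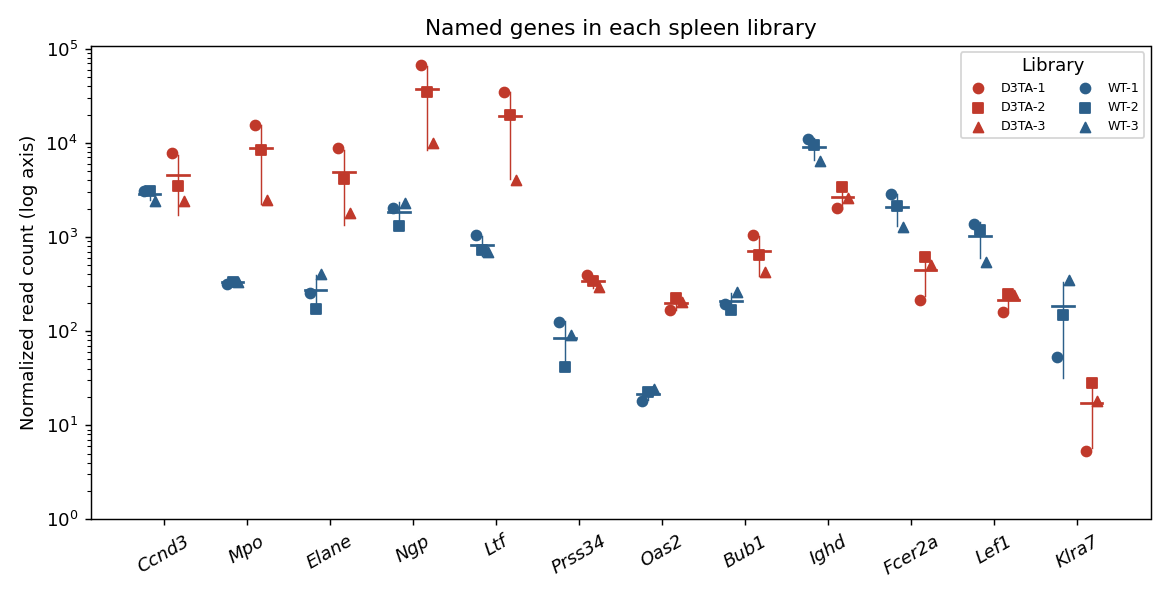
Normalized read counts of 12 named genes in each library on a log axis (red D3TA, blue WT). Points are libraries, horizontal lines are group means and vertical lines are 1 SD, drawn no lower than 1. Mpo lies at 2457 to 15516 in D3TA and 320 to 334 in WT, and Ighd at 2024 to 3398 in D3TA and 6356 to 10945 in WT.

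Other myeloid lists split between members. Of 16 monocyte genes 8 lay above 0, the median difference was 0.02 and the mean 0.07, while camera's direction was down (adjusted p 0.835). Ly6c2 and Ccr2, both marking inflammatory monocytes, rose over the list alone, by 2.37-fold (4537 ± 899 against 1927 ± 478) and 2.91-fold (1212 ± 366 against 432 ± 175; SD, n = 3 each). F13a1, named after its values were seen, made up the rest of the 3 that rose, at 759 against 166. The count of 3 became 0 without D3TA-2 and without WT-2, 1 without D3TA-1 and 2 without WT-3. Ly6c2 reads can be shared with its close copy Ly6c1. Of 14 basophil, mast cell and eosinophil genes, 2 rose and 1 fell over the list alone, and the list was not called (adjusted p 0.0929). It was called without D3TA-1 (0.0359) and without WT-3 (0.00669), where the adjusted p = 0.632 and 0.555 with an estimated correlation. The count of 2 that rose became 5 without WT-3 and 3 without D3TA-3 or WT-1. The basophil, mast cell and eosinophil score difference was -0.37 between high-hemoglobin and 1.72 between low-hemoglobin libraries, and the monocyte score difference was -0.26 and 0.42. Prss34 and Mcpt8, proteases of basophils, were 4.31-fold and 4.97-fold higher, at 340 ± 49.3 against 85.2 ± 41.6 and 200 ± 28.6 against 45.3 ± 25.3. Il5ra, the interleukin-5 receptor chain of eosinophils and some B cells, was the member that fell, from 168 to 48.5, and was named after its values were seen.

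Macrophage and dendritic cell lists lay lower in D3TA. Of 17 red pulp macrophage genes 15 lay below 0, at a mean of -0.30 with a camera adjusted p of 0.0143 (adjusted p = 0.570 with an estimated correlation), lost without D3TA-1 (0.715, with a mean of 0.00083 and 11 of 17 members above 0) and without WT-3 (0.511, with a mean of -0.03 and 8 above 0). Hpgd averaged 938 ± 313 in D3TA and 2098 ± 1001 in WT, and the scavenger receptor Marco 1237 ± 362 and 2025 ± 542. Of 14 dendritic cell genes 10 lay below 0, at a mean of -0.57 with a camera adjusted p of 0.0447 (adjusted p = 0.570 with an estimated correlation), which was over 0.05 without D3TA-1 (0.561), WT-1 (0.0920), WT-2 (0.0595) or WT-3 (0.0919) and with the hemoglobin term (0.284) or the Y-linked term (0.0547). The macrophage and dendritic score differences were -1.05 and -0.95 between high-hemoglobin libraries and 0.39 and 0.20 between low-hemoglobin libraries. Klk1 fell over the list alone, from 88.0 ± 27.8 to 11.4 ± 9.12. The count of 1 became 0 without D3TA-2, WT-1, WT-2 or WT-3 and with the hemoglobin term, and 4 without D3TA-3. Cd209a averaged 53.1 ± 71.1 in D3TA and 169 ± 38.6 in WT (SD, n = 3 each).

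Interferon response genes included 3 that rose over the list alone, among 20 tested and 14 above 0. Oas2, an antiviral oligoadenylate synthetase, was 8.80-fold higher, at 198 ± 30.3 in D3TA and 21.6 ± 3.09 in WT (SD, n = 3 each), with an adjusted p of 0.0945 over all genes. Oas3 and Rsad2, named after their values were seen, averaged 788 against 187 and 4626 against 1306. The list mean was 0.72 higher with a camera adjusted p of 0.000546 (adjusted p = 0.553 with an estimated correlation). The call was lost without D3TA-3 (0.395), and the difference was 0.18 between high-hemoglobin and 1.51 between low-hemoglobin libraries. The count of 3 became 5 without WT-3 and 2 without D3TA-1, D3TA-2, WT-1 or WT-2.

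Several fixed lists were not called. Stem and progenitor genes had 10 of 18 members above 0 (adjusted p 0.552), with Prom1 at 271 ± 174 in D3TA and 39.5 ± 22.0 in WT, and Hoxa9 at 28.4 ± 20.03 and 3.94 ± 4.57 (SD, n = 3 each). Myeloid and erythroid transcription factors had 14 of 18 above 0 (adjusted p 0.0933). They were called higher without D3TA-2 (0.0353), D3TA-3 (0.00229, with 6 members rising over the list alone) or WT-2 (0.0458), and the adjusted p = 0.563, 0.421 and 0.604 with an estimated correlation. Cebpe, which drives granule gene expression in maturing neutrophils, was at 1867, 1234 and 217 in D3TA-1 to D3TA-3 and at 48.7, 0 and 130 in WT-1 to WT-3. JAK-STAT feedback genes had 10 of 18 above 0 (adjusted p 0.871), with Pim1 at 4597 ± 3467 and 1564 ± 140. Without D3TA-3, 2 stem and progenitor genes and 2 JAK-STAT genes rose over the list alone. Inflammatory cytokine genes had 13 of 18 above 0 (adjusted p 0.552), with Cxcl1 at 4.30 ± 3.36 and 29.4 ± 32.7. The cytokine list was called higher without D3TA-1 (0.0359, and adjusted p = 0.660 with an estimated correlation), and its mean was -0.13 without D3TA-3. Fibrosis genes had 12 of 17 above 0 (adjusted p 0.0784), with Col5a1 at 557 ± 446 and 168 ± 47.5. The fibrosis list was called higher without D3TA-1 (0.0166), D3TA-2 (0.00914), WT-1 (0.0225) or WT-2 (0.0140), but lay at 0.720 without D3TA-3 and 0.734 without WT-3. For those 4 calls the adjusted p = 0.770, 0.563, 0.661 and 0.604 with an estimated correlation. It was also called with the Y-linked term (0.0360) and with the hemoglobin term (9.20e-05, with 9 members rising over the list alone), where the adjusted p = 0.568 and 0.328 with an estimated correlation. Stroma and endothelium genes had 9 of 18 above 0 (adjusted p 0.222), with the chemokines Cxcl12 at 4159 ± 1481 and 8102 ± 1313 and Cxcl13 at 1650 ± 863 and 5742 ± 4055. The stroma list was called lower without D3TA-3 (0.00662, with 3 members falling over the list alone) and without WT-3 (0.0139), and the adjusted p = 0.478 and 0.611 with an estimated correlation. With the hemoglobin term its mean turned from -0.17 to 0.23, with 2 members rising over the list alone, and its mean was 0.14 without D3TA-1 and 0.05 without WT-1.

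Lists that track tissue handling and neighbouring tissue were measured beside these. Immediate early and heat shock genes were not called (adjusted p 0.324), and Fos averaged 128 ± 8.20 in D3TA and 51.8 ± 18.6 in WT. Mitochondrially encoded genes had 10 of 12 members below 0 (camera adjusted p 0.0212, and adjusted p = 0.570 with an estimated correlation), with mt-Co3 at 313, 313 and 251 in D3TA-1 to D3TA-3 and at 440, 1233 and 578 in WT-1 to WT-3. Without WT-2 that list's direction was up (adjusted p 0.722), and the call was lost with the hemoglobin term (0.337) and without D3TA-3 (0.0603). Its score difference was 0.77 between high-hemoglobin and -1.003 between low-hemoglobin libraries, and 7 of the 12 members lay above 0 with the hemoglobin term. Adipocyte genes had 5 tested members and were not called (adjusted p 0.222), with Fabp4 at 187 ± 50.1 and 802 ± 581, and Pck1 at 44.8 in WT-2 and at most 16.4 elsewhere. The adipocyte list was called lower without WT-1 (0.00119, with 2 members falling over the list alone, and adjusted p = 0.661 with an estimated correlation), and its mean turned from -0.69 to 0.78 without WT-2. No pancreatic acinar gene passed the filter on low values.

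The lists share replicate spread, and 3 libraries against 3 allow no exact 2-sided permutation p below 0.1 for any list score. A change in a list is a change in its transcripts, since cell numbers were not measured in these libraries.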

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

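The terms for Y-linked reads and hemoglobin share, the pseudocounts, TMM factors and filterByExpr in the limma fit, and estimated correlations with the block, with a term or with a library left out were chosen after the data were seen. The fit without both D3TA-1 and WT-2 was chosen then too. The edgeR test, planned as the main test, became an alternative once the unit was known. The count of 0 genes in limma (1542 at an unadjusted p under 0.05) held under the 4 other scalings, both pseudocounts, the count filters, limma-voom and edgeR. It became 472 with DESeq2 (without the count filter), 44 in limma with no filter, 15 with the Y-linked term and 11 with the hemoglobin term. With 1 library left out it ranged from 0 to 306, the 306 being without D3TA-3. The cause was not tested. Scaling by library size only moved the median of all genes from 0.06 to 0.15 and left the count of 17 lists. With an estimated correlation or with fry, 0 of the 17 lists were called (fry's test for change in either direction called 2, monocyte and interferon response). Over the other settings, apart from the fit without both D3TA-1 and WT-2, the lists called ranged from 16 to 19. With 1 library left out they ranged from 14 to 19. Without both D3TA-1 and WT-2, the erythroid (camera adjusted p 0.541), heme (0.707), plasma cell (0.1005) and T cell (0.422) calls were lost. The red pulp macrophage (0.0514), dendritic cell (0.707) and mitochondrially encoded (0.635) calls were lost too. In that fit the basophil, mast cell and eosinophil (0.0380) and fibrosis (0.00142) lists were called higher (adjusted p = 0.485 and 0.747 with an estimated correlation). With an estimated correlation, no list was called with 1 library left out or with either term (smallest adjusted p 0.231). The mitochondrially encoded list lost its call without WT-2, where its direction, not past the threshold, was up, its adjusted p ranging from 5.13e-07 (without WT-3) to 0.722 (without WT-2) with 1 library left out. Pck1, at 1.66 in limma, was at -0.41 in edgeR and -0.43 in DESeq2, its WT reads lying in WT-2 alone. Ccnd3 stayed above 0 under each setting, from 0.04 without D3TA-1 to 0.88 without D3TA-3, and at 0.68 with DESeq2. DESeq2 called 25 of the 43 named genes, Mpo (4.74), Ltf (4.57), Ighd (-1.74) and Bub1 (1.77) among them.

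Same-numbered libraries did not deviate together, with correlations of -0.06, -0.0046 and -0.13 across genes, and no library correlated best with its own number. With the replicate block, limma called 0 genes (1475 at an unadjusted p under 0.05), edgeR 0, and camera 17 lists, of which 0 were called with an estimated correlation. Counts over the list alone moved with the block from 0 to 3 (G1/S) and 0 to 1 (erythroid) rising, and from 1 to 3 (dendritic cell), 1 to 4 (NK), 1 to 2 (plasma cell), 0 to 1 (monocyte) and 15 to 14 (B cell) falling.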

Other observations

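Outside the fixed lists, several genes chosen after their values were seen stood well apart between groups. Gpat2, a glycerol-3-phosphate acyltransferase best known from testis, was at 57.8, 173 and 201 in D3TA-1 to D3TA-3 and at 2.87, 0 and 3.87 in WT-1 to WT-3 (adjusted p 0.0945 in limma, 8.34e-10 in DESeq2). Lin28a, an RNA-binding protein of fetal and stem cells, was at 461, 259 and 56.2 in D3TA and at 3.82, 0 and 11.6 in WT (adjusted p 0.112 and 0.00433). Olr1, an oxidized-lipoprotein receptor, was at 108, 47.5 and 19.0 in D3TA and listed at 0 in each WT library.

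A further 4 single genes, chosen because their values were seen to be lower in D3TA and not as a group, did not pass in limma, while DESeq2 called Vpreb3 (adjusted p 2.85e-06) and Klf2 (0.0392). Vpreb3, expressed in B cell development, averaged 98.0 ± 48.1 in D3TA and 625 ± 176 in WT (6.72-fold lower, adjusted p 0.0945). Ccr7, a chemokine receptor, averaged 797 ± 466 and 2200 ± 72.4, S1pr1, a sphingosine-1-phosphate receptor, 1256 ± 516 and 2857 ± 312, and Klf2, a transcription factor, 2474 ± 502 and 5426 ± 702 (SD, n = 3 each).

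Of the tests that follow, those for B cell share, sex, blood left in the spleen and erythroid precursors were chosen only after the result was seen. With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 1542 genes at an unadjusted p under 0.05 and the highest other split 2096. With the real one included, 2 of the 10 gave 1542 or more. That other split set D3TA-1, D3TA-2 and WT-3 against the rest and is the split by hemoglobin share. With a term for that share, genotype gave 1461 such genes. For lists, the real split gave 17 and the highest other 21, and 3 of the 10, the real one included, gave 17 or more.

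Higher neutrophil granule transcripts in D3TA were set against 3 other explanations. A lower share of B cells would lift all other transcripts alike, but the secondary granule score minus the T cell score still differed by 4.03 ± 1.34 (SE, log2). The T cell score itself differed by -0.66 ± 0.57 (SE), so part of the 4.03 is a T cell fall. Both scores were known when this test was chosen, and T cell genes may not be a neutral reference. The values show only that these lists did not rise alike. Sex of the animals would leave little difference within the same sex. Among the 4 libraries without Y-linked reads the secondary granule score differed by 4.27 ± 0.72 (SE), and between the 2 with them by 1.58. Of those 4, WT-2 scored 6.66 and WT-3 8.04, so the 4.27 leans on WT-2. The 2 with Y-linked reads were D3TA-3 and WT-1, and a term for this balanced split left the mean difference at 3.37. So few libraries cannot fix the size of the difference within a sex. More blood left in D3TA spleens would tie the difference to hemoglobin. With the hemoglobin term the granule difference was 2.88 ± 0.60 (SE), against 3.37 ± 0.85 without. That cannot settle the explanation. Hemoglobin genes are also members of the erythroid list, which camera called higher in D3TA, so their share does not measure blood alone. WT-3 was the only WT library with a high share and D3TA-3 the only D3TA library with a low share. More granulocytic cells in the D3TA spleens stays open as a hypothesis, untested because cell counts were not used here, and chance stays open too.

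Higher mitotic transcripts in D3TA may come with more dividing precursors of a given lineage. At equal erythroid score the G2/M difference was 1.008 ± 0.343 (SE), against 1.501 ± 0.505 without it. The erythroid list holds hemoglobin and other genes that do not mark dividing cells alone, so its score is an imprecise stand-in for dividing precursors. A remaining difference therefore does not settle whether erythroid precursors were the source. At equal primary granule score the G2/M difference was -0.069 ± 0.819 (SE). Because the primary granule score separates the groups completely, granulocyte precursors and a genotype effect on the cell cycle cannot be told apart here.

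WT-2 listed 8449 genes at 0. Depth did not account for it, since the other 5 libraries thinned to its 14944622 reads reached at most 5369. Of genes with a mean of 20 to 100 in the other libraries, 13.004% were at 0 in WT-2, against 0.125% to 1.45% for each of the others, which may reflect fewer distinct RNA molecules. WT-3, at 1.45%, lay above the 1% set beforehand as the bound for the other libraries, so this stays open. WT-2 also carried adipocyte transcripts (Adipoq, chosen after its values were seen, at 260, against at most 8.64 elsewhere) and 18 Ddx3y reads beside 2348 Xist reads, and no biological explanation was tested.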
